A study of Mus musculus with 34 samples.

How the data were processed

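RNA of peripheral lung from 34 mice aged 2 weeks was measured on Affymetrix gene arrays, 1 array per mouse. Per the labels, the tissue was kept in RNAlater, and RNA was extracted with TRIzol and RNeasy and labelled with biotin. The deposited values are log2 signals, 1 per probe set and array, and the labels name Affymetrix Expression Console without a version, a summary method or a normalization. The scale was checked on the values: every array shares a floor of 4, and the array medians lie between 7.04 and 7.37 with a median of 7.25. The floor equals the log2 of an offset of 16, which was read from the values. The arrays did not share 1 distribution, so a plain quantile normalization of these values was ruled out.

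The table held 34891 probe sets, of which 23026 had an entry in the probe annotation. Probe sets with several symbols (1354) were left out, and 21672 probe sets with 1 symbol remained. Of these, 968 genes had more than 1 probe set, and the probe set with the highest mean signal was kept, which gave 19938 genes. The other 11865 probe sets were used in 1 alternative only. No further normalization or filter on level was applied, and 206 genes had a value at the floor in at least 1 array. Ddx3y, planned as a check of sex, was not analysed here.

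Samples were grouped by strain, exposure and sex as labelled, which gave 12 groups. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances and a trend of variance on level (22 residual and 7.83 prior degrees of freedom). The SE and p of a gene thus use 1 spread shared by all 12 groups, not the spread of the strain compared. Arsenic was compared with control in each strain with the labelled sexes at equal weight, averaged over the strains, and in each labelled sex. Differences of the arsenic effect between strains (F test and pairs) and between sexes were tested, as were differences among control mice between strains and sexes. The threshold was an adjusted p of 0.05 (Benjamini and Hochberg) over all genes of a comparison. Where a text says "over the list alone", the adjustment covered the genes of that list.

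Gene lists (31 lists with 662 entries, 616 of them measured) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. They include 8 genes recalled as named by the study, without a paper at hand to check them. They are called study-named below. Per-mouse means of each list were compared by permuting exposure within a strain, over all 924 splits of 6 against 6 mice or 210 splits of 6 against 4, and by 1e+05 random permutations for the mean over strains. The smallest exact p is 0.00216 for 6 against 6 and 0.00476 for 6 against 4. An SE given with a per-mouse list mean uses only the mice of both groups compared, not the shared spread. The lists, the comparisons and the settings were chosen before the data were examined. The per-mouse permutation of lists, the comparison without the 5 mice whose sex genes oppose their label, the comparison without C3H/HeARC control male 1 as a setting of its own, the mucous, club cell, cartilage and type 2 response lists, the lists tested between control strains, the secretory and mucus list without study-named genes, and the list tests with an estimated correlation and 1 mouse left out were chosen after.

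Genes were named by a fixed rule. In each strain comparison and their mean, the 12 largest rises and falls past the threshold were named, or the 10 smallest p as values where fewer than 10 genes passed. For each list, up to 4 members past the threshold over all genes were named, or otherwise the 2 with the smallest p. All study-named genes were named. In every other comparison the 5 largest rises and falls were named, or the 3 smallest p where none passed. Xist, Eif2s3y, Kdm5d and Uty were named for the check of sex, and predicted genes were counted only. Other members that passed over their list alone, the genes called when a mouse or setting was changed, Scgb1a1 and Acta1, and the control strain genes in the closing section were named after their values were seen.

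The analysis was tested on simulated data, in which each gene had its measured mean and spread, the noise was independent between genes and mice, and changes were added to 200 genes. A log2 change of 1 was recovered in 92.5% of genes in BALB/c, 85.1% in C3H/HeARC and 82.1% in C57BL/6, and a change of 0.5 in 32.8%, 50.7% and 20.9%. Each rate comes from a single random draw of 67 genes, so the rates do not rank the strains. The simulated spread was equal in all groups, so the rates can overstate recovery of genes whose spread differs between groups. Besides leaving out each of the 34 mice, 20 alternatives were tried, on the replicate number, normalization, filters on level, probe sets, variance model, array weights, model and list tests. Gene names were matched to RefSeq for 21584 probe sets. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.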

Results

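Gene expression was measured in peripheral lung of 34 mice aged 2 weeks, with 1 array per mouse. Their mothers had drunk water holding 100 µg/L arsenic, or control water with 0 µg/L, between gestation day 8 and birth, and all mothers drank control water afterwards. The mice came from 3 inbred strains, BALB/c, C3H/HeARC and C57BL/6, and from both sexes, which gave 12 groups of strain, exposure and sex. Each group held 3 mice, except C57BL/6 control females and C57BL/6 control males, where replicates 1 and 3 made 2 mice each. Over both sexes, arsenic and control held 6 and 6 mice in BALB/c, 6 and 6 in C3H/HeARC, and 6 and 4 in C57BL/6. The median log2 signal of an array lay between 7.04 and 7.37. The number of arrays limits the precision of every value, and it is not known which mice shared a litter, so every test treated the mice as independent.

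The C57BL/6 comparison asked which lung genes differed after exposure before birth in this strain, and the series names lung development and the clearance of mucus by cilia as its subject. In C57BL/6, products of airway mucous cells took 6 of the 10 places with the smallest p, all at higher levels in the arsenic group. The SDs given below differ between arsenic and control, while the model used 1 spread for all groups, so these p values are approximate. Clca1, a secreted protein of goblet cells, averaged 9.83 ± 2.70 (SD, n = 6) with arsenic and 5.92 ± 0.59 (SD, n = 4) in controls, a 15.1-fold ratio. Bpifb1, a secreted defence protein of airway glands and goblet cells, averaged 8.99 ± 2.50 (SD, n = 6) against 5.21 ± 0.08 (SD, n = 4), a 13.7-fold ratio. With 1 mouse left out, the log2 change lay between 3.16 and 5.05 for Clca1 and between 3.26 and 4.77 for Bpifb1. The control means of Bpifb1, Reg3g and Tff2 lie below the lower quartile of every array (5.76 to 6.13) and those of Clca1, Muc5b and Scgb3a1 within that range, near the signal of the Y-linked Kdm5d in mice without a Y signal (4.84 to 5.72), so each fold depends on the background. Reg3g, a secreted antibacterial lectin, averaged 8.20 ± 2.74 (SD, n = 6) against 5.06 ± 0.74 (SD, n = 4), and Scgb3a1, a secretoglobin of airway secretory cells, averaged 8.54 ± 1.97 (SD, n = 6) against 6.00 ± 0.18 (SD, n = 4). The mucin Muc5b differed by 1.66 (SE 0.37) and the trefoil peptide Tff2 by 1.71 (SE 0.38) on the log2 scale. The other 4 places went to Muc15, a membrane mucin, at -0.97 (SE 0.20), Pmvk, a kinase of cholesterol synthesis, at 0.64 (SE 0.14), the carboxylesterase Ces2g at -0.81 (SE 0.18) and the receptor Mrgprh at -0.81 (SE 0.21).

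None of the 19938 genes passed an adjusted p of 0.05 in C57BL/6 by limma, and 676 had an unadjusted p under 0.05, where 997 are given by chance alone. The smallest adjusted p was 0.31, held by Bpifb1 among others. Bpifb1 was above every control in 6 of 6 arsenic mice, Clca1, Tff2, Muc5b and Scgb3a1 in 5 of 6, and Reg3g in 4 of 6. These 6 genes are recalled as named by the study from the same samples, so their p values are no independent test. The mouse arsenic male 3 stayed near the controls, with Clca1 at 5.54 and Bpifb1 at 5.49, and without it 7 genes passed: Bpifb1 at 4.77 (SE 0.50, adjusted p = 2.9e-06), Clca1, Muc5b, Reg3g, Scgb3a1 and Tff2, and also Gsto1, a glutathione transferase that acts on arsenic species, at 0.74 (SE 0.14, adjusted p = 0.038). Every mouse was left out in turn, and arsenic male 3 stands out by its low values of these same genes. Leaving it out raises their difference and lowers their spread, so the p values without it are no test, for Gsto1 as well. Without control female 3, the olfactory receptor gene Olfr181 passed at -0.77 (SE 0.13), and without control male 1 the vomeronasal receptor gene Vmn1r51 at -1.19 (SE 0.18).

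**Figure D1:**
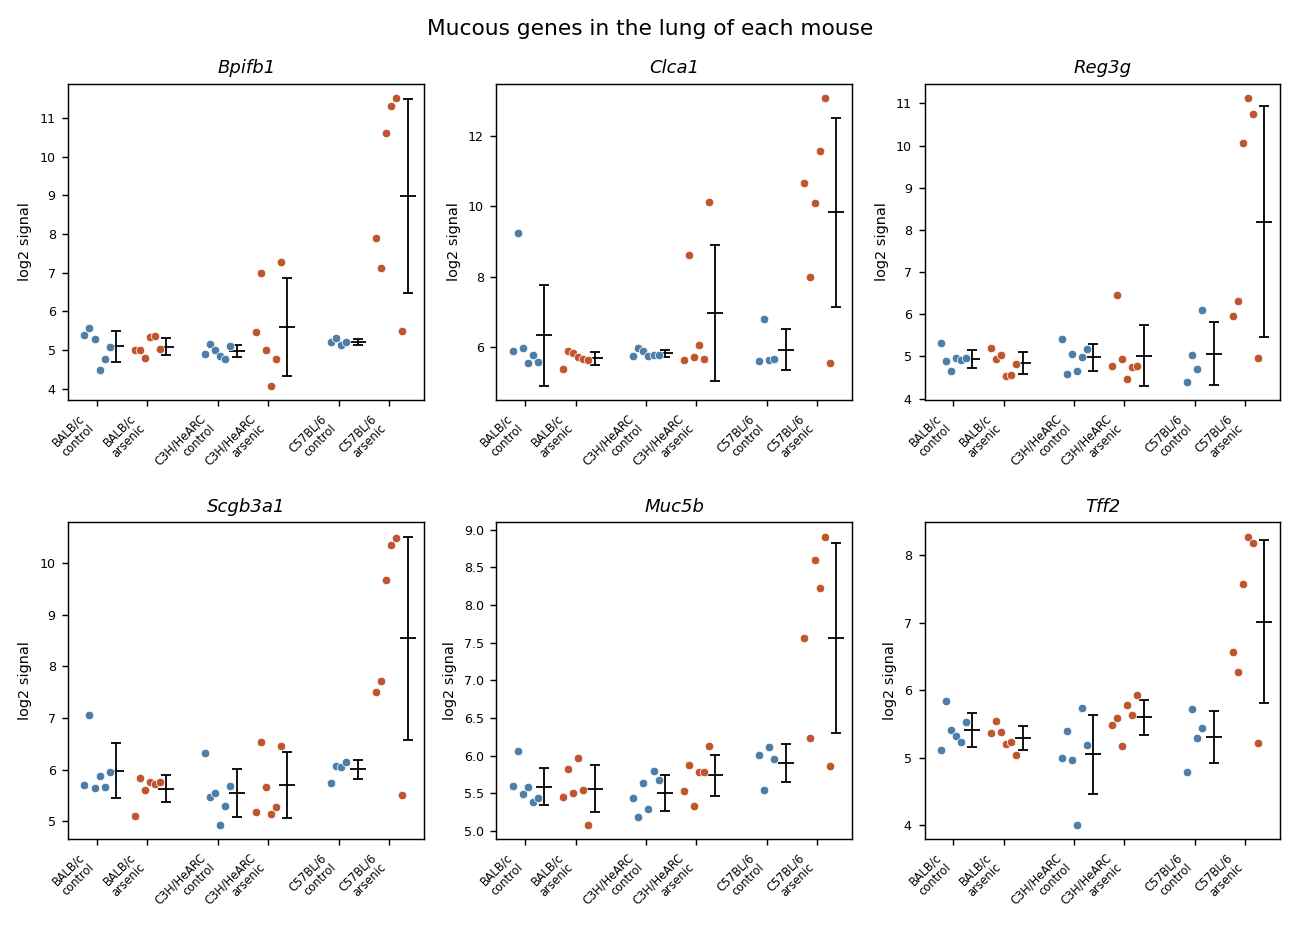
Log2 signal of Bpifb1, Clca1, Reg3g, Scgb3a1, Muc5b and Tff2, 1 point per mouse by strain and exposure, with the group mean and SD beside the points. Clca1 exceeded 7.9 in 5 of 6 C57BL/6 arsenic mice, and it was also high in BALB/c control female 2 at 9.24 and in C3H/HeARC arsenic male 3 at 10.1.

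Of 31 gene lists, 13 passed in C57BL/6 by camera with a preset correlation of 0.01, 7 upward and 6 downward, and 2 of them passed with an estimated correlation. The secretory and mucus list had a mean change of 0.79 over 29 measured genes, with 21 of 29 positive (adjusted p = 9.27e-15, and adjusted p = 0.0227 with an estimated correlation). With that correlation the call ended without arsenic male 2 (0.0896), control female 3 (0.116) or control male 3 (0.0613), and fry gave 0.081. Of the 29 genes, 6 are recalled as named by the study from these samples. Without them the other 23 had a mean change of 0.27 with 15 of 23 positive (adjusted p = 5.4e-05, but adjusted p = 0.238 with an estimated correlation). The call with an estimated correlation thus rests on those 6. Over the list alone, 9 of its 29 genes passed, all higher, among them the polymeric immunoglobulin receptor Pigr at 0.96 (SE 0.32) and the goblet cell mucin Muc5ac at 0.73 (SE 0.23), against 0 over all genes. Without the study-named genes, 3 of 23 passed over the list alone. Its median change was 0.23, and Scgb1a1, the main product of club cells, differed by 0.09 (SE 0.17). The 8 study-named genes were higher by a mean of 2.23 (adjusted p = 3.01e-22, and adjusted p = 0.005 with an estimated correlation), and 7 of 8 passed adjusted over the list alone. These 8 genes are recalled as chosen by the study on these samples, so these p values are not independent evidence. With genes below the median level left out, only Dynlrb2 of the 8 remained (adjusted p = 0.0682), which is no test of the list. An exact permutation of the list mean per mouse gave p = 0.0238 for the secretory and mucus list and p = 0.0381 for the study-named genes, with an adjusted p of 0.394 over 31 lists.

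The 60 measured genes of motile cilia, the beating structures that carry mucus, had a mean change of 0.31 in C57BL/6 and 53 of 60 were positive (adjusted p = 3.87e-14, but adjusted p = 0.384 with an estimated correlation, and 0.0746 among genes above the median level). Examples were Enkur at 0.54 (SE 0.20) and the axonemal dynein chain Dnaic1 at 0.62 (SE 0.23), and 0 passed adjusted over the list alone. Glucocorticoid response genes had a mean change of 0.49, with 11 of 12 positive, as for the receptor co-chaperone Fkbp5 at 0.99 (SE 0.36) and the stress gene Ddit4 at 0.58 (SE 0.19) (adjusted p = 2.18e-09, but adjusted p = 0.115 with an estimated correlation). NRF2 and glutathione genes, an antioxidant programme, had a mean change of 0.14 with 22 of 27 positive (adjusted p = 4.75e-05, but adjusted p = 0.403 with an estimated correlation, and a mean of 0.09 without the 5 mice whose sex genes oppose their label), including the glutathione transferase Gsta3 at 0.57 (SE 0.25). Mt1, a metal-binding metallothionein, at 0.61 (SE 0.19) and Gsto1 at 0.58 (SE 0.16) passed adjusted over their lists alone, while those lists did not pass.

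Each of the other 8 lists past the threshold in C57BL/6 lost its call when single mice of this strain were left out. Macrophage genes averaged 0.19 (Marco, a scavenger receptor, 0.60, SE 0.22), with 0.12 (adjusted p = 0.135) without control female 3 and 0.07 (adjusted p = 0.503) without the 5 mice whose sex genes oppose their label. Endothelial genes averaged -0.12 (the vascular growth factor receptor Kdr -0.38, SE 0.12), with -0.05 (adjusted p = 0.138) without control male 1 and -0.07 (0.0901) without arsenic female 1. The mean was -0.19 without control male 3 and -0.18 without the 5 mice. Elastin and collagen genes averaged -0.19 (Col6a3 -0.72, SE 0.20), with -0.11 (adjusted p = 0.146) without control female 1 and -0.11 (0.0881) without arsenic male 2. The mean was -0.13 without control male 1, -0.31 without arsenic male 3 and -0.29 without the 5 mice. Lung development regulators averaged -0.07 (Spry2, an antagonist of fibroblast growth factor signalling, -0.34, SE 0.11), with -0.03 (adjusted p = 0.463) and -0.02 (0.418) without control female 1 and control male 1. The mean was -0.06 (0.135) and -0.05 (0.197) without arsenic female 1 and arsenic male 2, and -0.12 without control female 3 or control male 3. Erythroid genes averaged -0.29 (Slc4a1, the red cell anion exchanger, -0.51, SE 0.28), with -0.08 (adjusted p = 0.746) without control female 3 and -0.08 (0.813) without the 5 mice. The mean was -0.22 (0.0958) and -0.24 (0.0583) without control male 1 and arsenic male 2, and -0.51 without control female 1. Cell cycle genes averaged -0.15 (E2f1 -0.34, SE 0.20) and turned to 0.03 (adjusted p = 0.465) without arsenic male 2. They had -0.10 (0.195) without arsenic female 3, 0.104 and 0.0958 as adjusted p without control female 1 and control male 1, and -0.26 without arsenic male 3. Circadian clock genes averaged 0.08 (Cry1 0.31, SE 0.15), with 0.03 (adjusted p = 0.231) without arsenic female 3 and 0.14 without arsenic female 1. The adjusted p was 0.0929, 0.0914, 0.0647, 0.118 and 0.0882 without arsenic male 3, control female 1, control female 3, control male 1 and the 5 mice. Immediate early genes averaged -0.17 (Nr4a1 -0.75, SE 0.34), with -0.08 (adjusted p = 0.38) without control male 1 and -0.26 without control male 3. The adjusted p was 0.135 and 0.267 without control female 3 and the 5 mice, and 0.107, 0.0502, 0.0933 and 0.212 without arsenic female 1, female 2, male 1 and male 3. With an estimated correlation, the adjusted p of these 8 lists lay between 0.533 and 0.745.

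In C3H/HeARC, the motile cilia list had a mean change of 0.39 and a median of 0.43, with 56 of 60 genes positive (adjusted p = 7.51e-19, but adjusted p = 0.238 with an estimated correlation). Over the list alone, 8 of 60 genes passed, all higher, against 0 over all genes. Dynlrb2, a dynein light chain, averaged 8.69 ± 0.52 (SD, n = 6) with arsenic and 7.45 ± 0.96 (SD, n = 6) in controls, and Lrriq1, another ciliary gene, averaged 6.29 ± 0.14 (SD, n = 6) against 5.64 ± 0.49 (SD, n = 6). The secretory and mucus list had a mean change of 0.29 with 22 of 29 positive (adjusted p = 1.83e-05, but adjusted p = 0.238 with an estimated correlation), and 5 of 29 passed adjusted over the list alone. Those 5 included the club cell enzyme Cyp2f2 at 0.83 (SE 0.24) and the airway epithelial receptor subunit Gabrp at 0.99 (SE 0.28). Sox2, a transcription factor of the conducting airways, differed by 1.18 (SE 0.32), and like Dynlrb2 it is recalled as named by the study from these samples. Exact permutations of the list mean per mouse gave p = 0.0758 for motile cilia and p = 0.0779 for secretory and mucus (adjusted p = 0.336 over 31 lists for both). Basal and neuroendocrine epithelium averaged -0.11 (adjusted p = 0.122). Without arsenic male 3 the secretory and mucus mean was 0.19. In 2 control mice, female 2 and male 1, the mean of the cilia genes was 6.27 and 6.01, and the other control mice lay between 6.74 and 7.16.

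None of the 19938 genes passed in C3H/HeARC by limma, and 936 had an unadjusted p under 0.05. The smallest adjusted p, 0.185, belonged to Oat, ornithine aminotransferase, at 0.42 (SE 0.08) and Adk, adenosine kinase, at 0.44 (SE 0.09). Ttc21a, at 0.78 (SE 0.16), the plasma protein Itih4, at 0.63 (SE 0.14), the epithelial keratin Krt8, at 0.50 (SE 0.11), and Nucb2, at 0.37 (SE 0.09), were also among the 10 smallest p, with Cyth1 at -0.63 (SE 0.14) and Zmat3, a target of p53, at -0.62 (SE 0.14). With quantile normalization 1 gene passed (Oat), and with array weights 5 passed (Oat, Adk and Krt8 higher, Zmat3 and C4bp-ps1 lower). In this strain Clca1 reached 8.63 in arsenic female 2 and 10.1 in arsenic male 3.

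Of the 31 lists, 15 passed in C3H/HeARC with the preset correlation, 12 upward and 3 downward, and 0 with an estimated correlation. The surfactant-producing type 2 alveolar list averaged 0.20 with 18 of 20 positive (Sftpa1 0.32, SE 0.11), the mesothelium list 0.35 with 10 of 10 positive (Upk1b 0.39, SE 0.15) and the NRF2 and glutathione list 0.17 with 24 of 27 positive (Tkt 0.31, SE 0.10). Cholesterol synthesis averaged 0.20 with 15 of 16 positive (Sqle 0.43, SE 0.14), metallothionein and heat shock 0.18 with 13 of 15 positive (Hspa1a 0.40, SE 0.13), and xenobiotic enzymes 0.18 with 10 of 12 positive (Ephx1 0.24, SE 0.11), or 0.11 without control male 1. Their adjusted p was 0.238 to 0.241 with an estimated correlation, and 2 genes of the cholesterol list and 2 of the heat shock list passed adjusted over the list alone. The study-named genes averaged 0.65 with 8 of 8 positive (adjusted p = 0.000556, but adjusted p = 0.296 with an estimated correlation, and a mean of 0.41 without arsenic male 3). The cell cycle list averaged 0.20 with 29 of 29 positive (Bub1, a spindle checkpoint kinase, 0.52, SE 0.24), but 0.11 (adjusted p = 0.121) without arsenic female 3. Type 1 alveolar genes (0.09, Ager 0.22, SE 0.10) had 0.05 (adjusted p = 0.171) without arsenic male 1 and 0.06 (0.0582) without control male 1. The adjusted p was 0.171 and 0.102 without control female 3 and control male 3, and the mean 0.14 without control male 2. Type 1 genes averaged 0.01 (0.478) with array weights, 0.05 (0.144) with cyclic loess and 0.07 (0.16) with quantile normalization. T and NK cell genes (-0.11, Il2rb -0.45, SE 0.16) had -0.04 (adjusted p = 0.186), -0.06 (0.0893) and -0.08 (0.0535) without control female 3, control male 3 and arsenic male 1, and -0.19 without control male 1. Immediate early genes (0.14, Ccn1 0.42, SE 0.23) averaged 0.06 to 0.08 with adjusted p values of 0.508, 0.486, 0.478 and 0.482 without arsenic male 1, arsenic female 3, control female 2 and control male 3, and 0.0504 to 0.0528 without BALB/c arsenic female 1 or C57BL/6 control females 1 or 3. With array weights these immediate early genes averaged 0.01 (0.705). Their adjusted p was 0.129 with quantile normalization, 0.0939 with cyclic loess and 0.0566 with array medians subtracted. Muscle genes averaged -0.54 and adipose genes -0.26, and both came from control male 1, where skeletal actin Acta1 was 15.5 against a median of 5.99 over all mice. Without that mouse the means were -0.01 (adjusted p = 0.632) and -0.03 (adjusted p = 0.925), and the cilia list averaged 0.24 with the labelled sexes at equal weight. Without control male 3 the muscle mean was -0.86. The adipose list also had 0.184, 0.125, 0.101 and 0.0586 without arsenic female 3, arsenic male 1, control female 1 and control female 3. With an estimated correlation, these 6 lists had adjusted p values from 0.238 to 0.669.

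**Figure D2:**
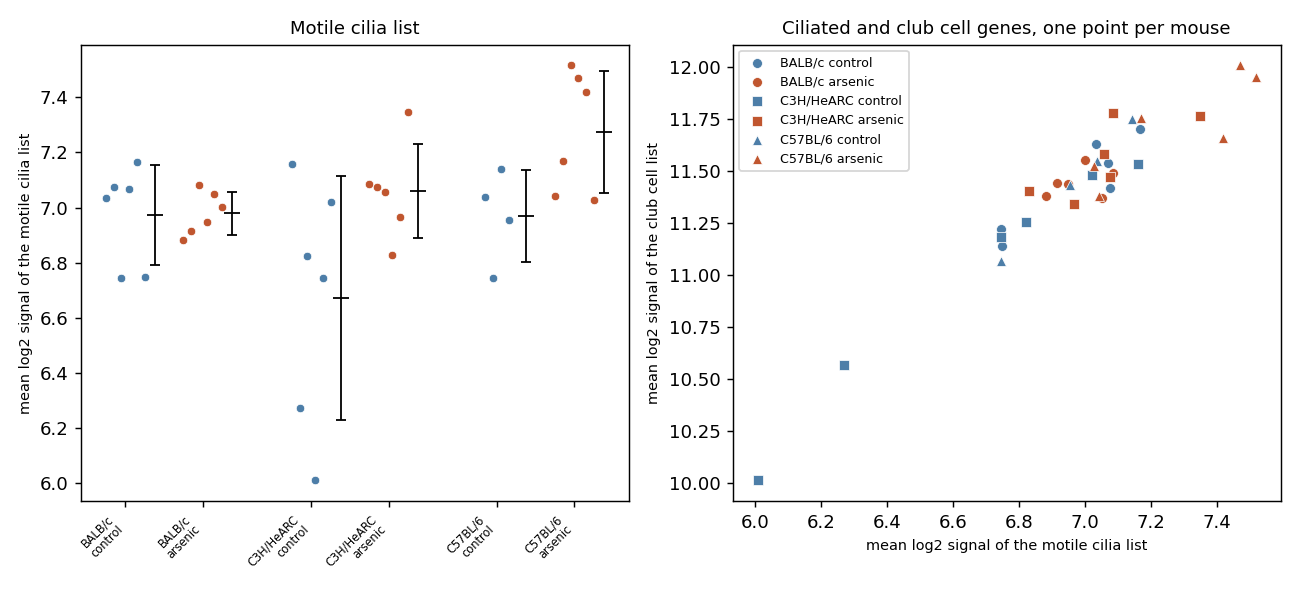
Left, mean log2 signal of the 60 motile cilia genes, 1 point per mouse by strain and exposure, with the group mean and SD. Right, the mean log2 signal of 7 club cell genes against that of the cilia genes, 1 point per mouse; C3H/HeARC control male 1 is lowest on both axes, at 6.01 and 10.01.

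In BALB/c, 0 of the 8 study-named genes had a positive change, with a mean of -0.20 (adjusted p = 0.161, and adjusted p = 0.887 with an estimated correlation). Clca1 averaged 0.65 lower on the log2 scale with arsenic (-0.65, SE 0.84), since control female 2 alone stood at 9.24, and Bpifb1 differed by -0.01 (SE 0.66). Both SEs use the spread shared by all groups, and with 1 mouse left out the Bpifb1 change lay between -0.08 and 0.07. The motile cilia list had a mean change of 0.01 with 35 of 60 genes positive (adjusted p = 0.429), and the secretory and mucus list -0.09 with 11 of 29 positive (adjusted p = 0.115). None of the 19938 genes passed by limma, and 548 had an unadjusted p under 0.05. The 10 smallest p, all with an adjusted p of 0.992, belonged to Pld6 (-0.48, SE 0.12), Ssxb10 (1.27, SE 0.34), the chemokine receptor Cxcr4 (0.32, SE 0.09), spermine oxidase Smox (0.39, SE 0.11), Snph, Ascl5, Abtb2, Dmrta1, Psg29 and Cntn1. Of the 31 lists, 3 passed with the preset correlation and 0 with an estimated correlation (adjusted p = 0.887 for each). Immediate early genes averaged 0.28 with 17 of 18 positive, as for the transcription factor Egr1 at 0.75 (SE 0.26) and the matrix protein Ccn1 at 0.69 (SE 0.23). Cholesterol synthesis genes averaged 0.18 with 16 of 16 positive, as for Fdps at 0.25 (SE 0.11), and 0.10 without control male 3. Glucocorticoid response genes averaged -0.22 with 2 of 12 positive, as for Per1 at -0.45 (SE 0.23). The glucocorticoid call rested on control female 1, at 10.25 against 9.09 to 9.50 in the other controls, and without it the mean was -0.04 (adjusted p = 0.336).

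Averaged over the 3 strains with equal weight, the comparison gave the mean effect, in which the study-named genes and the secretory and mucus list were positive in C57BL/6 and C3H/HeARC and negative in BALB/c. Other lists were not shared by the strains either. In C57BL/6, cholesterol synthesis averaged 0.001, type 2 alveolar epithelium 0.02, and metallothionein and heat shock -0.02. In BALB/c, motile cilia averaged 0.01, macrophage -0.03 and xenobiotic enzymes 0.0002. NRF2 and glutathione was positive in each strain, at 0.05 in BALB/c, 0.17 in C3H/HeARC and 0.14 in C57BL/6. The 9 lists past the threshold were all upward: motile cilia (mean 0.23, 57 of 60 positive), secretory and mucus (0.33, 22 of 29), study-named genes (0.89, 8 of 8), NRF2 and glutathione (0.12, 23 of 27), cholesterol synthesis (0.13, 16 of 16), type 2 alveolar epithelium (0.09, 19 of 20), macrophage (0.09, 16 of 18), metallothionein and heat shock (0.07, 12 of 15) and xenobiotic enzymes (0.08, 10 of 12). With an estimated correlation 0 of them passed, with adjusted p values from 0.0808 for the study-named genes, 0.127 for secretory and mucus, and 0.172 for both motile cilia and NRF2 and glutathione, to 0.635 for macrophage. Without the study-named genes, the secretory and mucus list averaged 0.15 (adjusted p = 0.000109, but adjusted p = 0.214 with an estimated correlation). The macrophage list had 0.0951 without C3H/HeARC control male 2 and 0.0748 without C57BL/6 control female 3. Metallothionein and heat shock lost the call without any of 14 mice, up to 0.222 without C57BL/6 control female 3, and xenobiotic enzymes without any of 12, up to 0.0875 without C3H/HeARC arsenic female 1. With quantile normalization the adjusted p was 0.323 for metallothionein and heat shock and 0.0634 for xenobiotic enzymes. The former also had 0.046 (0.306) with cyclic loess, and adjusted p values of 0.122 with the mean of probe sets and 0.341 with genes above the median level. Without the 5 mice whose sex genes oppose their label, both lists averaged 0.04 (adjusted p = 0.181 for metallothionein and heat shock and 0.32 for xenobiotic enzymes). Adjusted over the list alone, 6 cilia genes passed (Cfap52 0.44, SE 0.12, and Enkur 0.37, SE 0.11), 7 secretory genes (Bpifb1 1.47, SE 0.40, and Tff2 0.71, SE 0.20), 8 of 8 study-named genes, 2 cholesterol genes (Sqle 0.28, SE 0.08), the chemokine Ccl3 (0.39, SE 0.10) and Lcn2 (0.26, SE 0.08). Permuting exposure within strains, the mean list value per mouse gave p = 0.00242 for NRF2 and glutathione, p = 0.00904 for motile cilia, p = 0.0131 for study-named genes and p = 0.0136 for secretory and mucus (permutation tests, adjusted p = 0.075 to 0.105 over 31 lists). Over all genes 0 of 19938 passed by limma and 818 had an unadjusted p under 0.05, with an adjusted p of 0.999 for the 10 smallest: Coro2a, Krt8, Ttc21a, Ccl3, Cfap52, Anxa8, Lrrc34, Bpifb1, Wdr54 and Ccdc189. Without C57BL/6 arsenic male 3, 3 passed: Bpifb1 (1.79, SE 0.26), Scgb3a1 (1.06, SE 0.19) and Tff2 (0.88, SE 0.14). That mouse stands out by low values of mucous genes, so these calls are no test.

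Whether the arsenic effect differed between strains was tested directly. With the preset correlation, 15 lists passed for C57BL/6 minus BALB/c, 16 for C57BL/6 minus C3H/HeARC and 10 for C3H/HeARC minus BALB/c. With an estimated correlation 3, 0 and 0 passed, and by fry 0 in each; the 3 were for C57BL/6 minus BALB/c. The study-named genes differed by 2.44 (adjusted p = 0.0155, and 0.0665 without C57BL/6 control female 3). The secretory and mucus list differed by 0.88 over 29 genes, with 9 genes past the threshold over the list alone (adjusted p = 0.0344, and up to 0.124 without any of 11 mice, the highest without C57BL/6 control female 3). Without the 6 study-named genes it differed by 0.33 over 23 genes (adjusted p = 2.4e-05, but adjusted p = 0.194 with an estimated correlation), with 0 past the threshold over the list alone. The glucocorticoid response genes differed by 0.71 (adjusted p = 0.048), but the call ended without any of 23 mice, with 0.183 without C57BL/6 control male 3, and without BALB/c control female 1 the difference was 0.53 (adjusted p = 0.11). Between C57BL/6 and C3H/HeARC, the secretory and mucus list without study-named genes differed by 0.02 (adjusted p = 0.977 by camera with the preset correlation). Its mean change was 0.27 in C57BL/6 and 0.25 in C3H/HeARC, so outside the study-named genes it was not particular to C57BL/6. Among single genes, the difference between C57BL/6 and BALB/c was 4.56 (SE 1.26) for Clca1, 3.78 (SE 0.99) for Bpifb1 and -0.98 (SE 0.25) for Ces2g, and that between C3H/HeARC and BALB/c was 1.45 (SE 0.41) for Dynlrb2 and -0.88 (SE 0.20) for Zmat3. Over all genes 0 passed the moderated F test of limma (646 at an unadjusted p under 0.05), and 0 passed in any of the 3 pairwise differences (689, 547 and 940 at an unadjusted p under 0.05 for C57BL/6 minus BALB/c, C57BL/6 minus C3H/HeARC and C3H/HeARC minus BALB/c). Without C57BL/6 arsenic male 3, 6 genes passed the F test: Bpifb1, Clca1, Muc5b, Reg3g, Scgb3a1 and Tff2. That mouse stands out by low values of these genes, so these calls are no test.

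The sex labels were compared with genes of the X and Y chromosomes. Xist, an RNA made from the inactive X chromosome, was at least 10.7 or at most 5.28, and Eif2s3y, a gene of the Y chromosome, was at most 4.46 in the former mice and at least 8.00 in the latter. In 5 of 34 mice these genes opposed the label: those labelled BALB/c control male 1 and 3 had high Xist, and those labelled C3H/HeARC control female 1, C57BL/6 arsenic female 2 and C57BL/6 control female 3 had high Eif2s3y. Uty and Kdm5d, also on the Y chromosome, followed Eif2s3y. All samples were kept in the groups of their labels, so the strain comparisons balanced the labelled sex only. By sex genes, the share of female-like mice was higher in control than in arsenic mice in BALB/c. It was lower in control mice in C3H/HeARC and C57BL/6. Exposure is thus partly mixed with sex in the comparisons of each strain. Between control females and control males as labelled, Xist differed by 3.44 (SE 0.95) and Eif2s3y by -2.56 (SE 0.70), with 0 of 19938 genes past the threshold by limma and 345 at an unadjusted p under 0.05. Without the 5 mice, 6 genes passed: Xist at 6.58 (SE 0.21), Eif2s3y at -4.87 (SE 0.16), Uty, Kdm5d and Srsy, and Kdm6a, an X-linked demethylase, at 0.74 (SE 0.14).

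**Figure D3:**
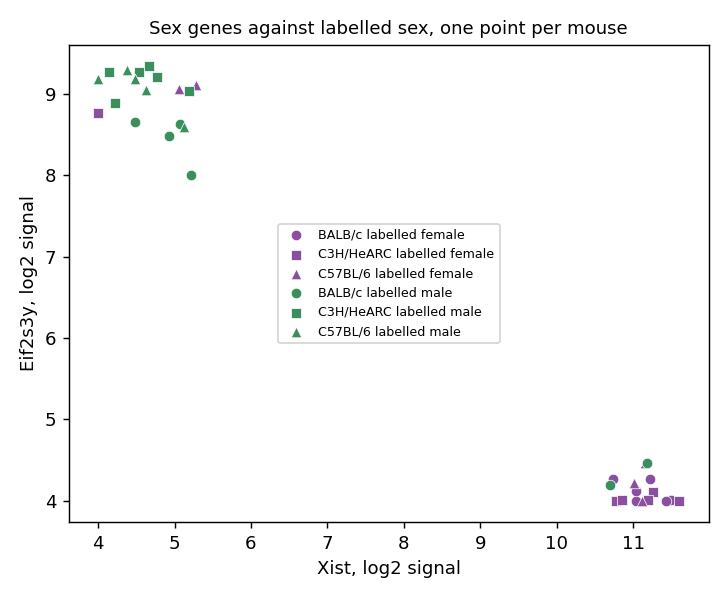
Log2 signal of Eif2s3y against that of Xist, 1 point per mouse, with colour for the labelled sex and shape for the strain. The mice form 2 groups, with Xist at most 5.28 or at least 10.7, and 5 of 34 mice fall in the group opposite to their label.

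The effect of arsenic was next compared between the labelled sexes, and here too the 5 opposing labels limit what each value means. As labelled, the difference between the female and male effects over the strains was -0.97 (SE 0.20) for the zinc finger gene Zfp94, -1.47 (SE 0.35) for the lipocalin Lcn15 and 0.83 (SE 0.21) for the protocadherin Pcdhb18. None of the 19938 genes passed by limma, and 1302 had an unadjusted p under 0.05. Without C3H/HeARC arsenic female 2, 1 gene passed, Lcn15 at -1.70 (SE 0.28). Within single labelled sexes of a strain, 0 genes passed by limma in any of the 6 comparisons, with between 120 (BALB/c males) and 1614 (C3H/HeARC females) genes at an unadjusted p under 0.05. Array weights gave 25 genes in at least 1 of the 6 comparisons, and leaving out C3H/HeARC arsenic female 2 gave 17.

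Control mice of the 3 strains were compared as the background against which the exposure was read. Against C57BL/6, the class II histocompatibility gene H2-Ea was higher by 6.92 (SE 0.16) in BALB/c and by 6.77 (SE 0.16) in C3H/HeARC, and the interferon-induced GTPase Gbp2b by 3.90 (SE 0.23) and 4.08 (SE 0.23). Trim12a, of a family of antiviral proteins, was lower than in C57BL/6 by -5.05 (SE 0.15) in BALB/c and -5.13 (SE 0.15) in C3H/HeARC, and Nxpe4 by -3.37 (SE 0.16) and -3.55 (SE 0.16). BALB/c controls also had more Fbp2, Ctse and Tbcb and less Zfand3 and Trim30d than C57BL/6 controls. C3H/HeARC controls had more Prg2, an eosinophil granule protein, at 3.26 (SE 0.29), Klk1b22 and Cytl1, and less Slc5a12 and less of the complement proteases C1s1 at -4.82 (SE 0.15) and C1s2. Against C3H/HeARC, BALB/c controls had more C1s1 at 4.72 (SE 0.14), C1s2, Tbcb, the complement component C4b and Tmem267, and less Zfand3 at -4.93 (SE 0.14), Klk1b22, Krt79, Serpina3n and Tubb3. Eif2s3y was lower in BALB/c than in C57BL/6 controls by -2.92 (SE 0.89), where 2 of the BALB/c labelled males lacked its signal and the mouse labelled C57BL/6 control female 3 carried it at 9.11.

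By limma, 1113 genes passed between BALB/c and C57BL/6 controls (749 higher and 364 lower in BALB/c), 1177 between C3H/HeARC and C57BL/6 (667 higher and 510 lower in C3H/HeARC) and 914 between BALB/c and C3H/HeARC (585 higher and 329 lower in BALB/c). The change exceeded 2-fold in 155, 207 and 132 of them. Without the 5 mice of opposing sex labels the counts were 363, 753 and 452, and with array weights 2488, 2207 and 2395. The first count fell to 430 without C57BL/6 control male 3, to 624 without C57BL/6 control female 3, to 658 without C57BL/6 control female 1, to 673 without BALB/c control male 2 and to 734 without BALB/c control female 1. The second fell to 663 and 695 without C57BL/6 control male 3 and control female 1, and the third to 594 without BALB/c control male 2. A sequence variant under a probe can lower the signal of a strain without a change in expression, so single genes of these comparisons cannot be read as expression differences on the arrays alone.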

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

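The tests of the secretory and mucus list without study-named genes, swapped sex labels, mixed RNA, wrong records, airway tissue in both strains and skeletal muscle were chosen only after the result was seen; those of another strain, cartilage and type 2 response were chosen after the patterns they bear on but before their own values were seen, and the other splits were planned.

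The 6 mucous genes of C57BL/6 were higher with arsenic by 2.79 (SE 0.823, n = 6 and 4), and since they are recalled as named by the study from these samples, no p of these genes is an independent test of the pattern. Cartilage genes, 0 of 13 on another list, differed by -0.0728 (SE 0.0884), which argues against cartilage-bearing airway, while airway without cartilage stays open. More airway tissue in the arsenic lung pieces cannot be told apart from the exposure: motile cilia and club cell genes were higher by 0.305 (SE 0.123) and 0.263 (SE 0.174), and although the mucous genes exceeded them by 2.48 (SE 0.759) and 2.52 (SE 0.798), all 6 lay near background in controls, so this difference decides nothing. A type 2 inflammatory response in the arsenic mice cannot be told apart from the exposure itself, since its list differed by 0.377 (SE 0.189, exact p = 0.138) and 5 of its 12 genes stand on other lists. Exposure, litter and an exchange of exposure labels remain open and untested.

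The ciliary genes of C3H/HeARC were higher with arsenic by 0.389 (SE 0.194, exact p = 0.0758), and club cell genes by 0.551 (SE 0.254, exact p = 0.0303), or 0.353 (SE 0.188, exact p = 0.0541) without control male 1. Less airway tissue in the C3H/HeARC control lung pieces cannot be told apart from the exposure. Over 12 mice, both lists moved together after group means were removed (r = 0.96, permutation p = 0.00014, and 0.919 without control male 1 and control female 1). Genes of both airway cell types can move together within groups with or without an effect of exposure. The removed group means held the difference to be explained, so this correlation decides nothing. The most abundant club cell genes Scgb1a1 and Cyp2f2 have median levels of 13.48 and 12.6, and 6 of the 7 club cell genes stand on another list. Skeletal muscle in control male 1 stays open, because without that mouse the cilia change, taken as the plain mean over mice, was 0.256 (SE 0.167, exact p = 0.13). An effect of exposure on the airway lining was not separated from either.

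In 5 mice the sex genes opposed the label. A swap of samples within a strain needs a partner of the other sex, and 0 of the 5 had a partner out of place in the other sex of its strain, which argues against such a swap. All 5 stood nearest their own strain over 200 genes, which argues against samples of another strain, and no sex gene lay more than 0.1 outside the range of matching mice, which argues against mixed RNA. Single animals recorded with the wrong sex, or exchanged with samples outside this set, cannot be told apart, as 5 of 5 lacked a partner. No biological explanation was tested.

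Of 186 groups of list values, 14 held a mouse far from the others, where chance gives about 1 in 20 groups, or 9.3, and 5 of the 14 were in C3H/HeARC control male 1. In that mouse the list means were 9.31 for muscle (others 5.91 to 6.40), 7.93 for adipose (6.33 to 6.59), 11.08 for elastin and collagen (10.26 to 10.39), 7.2 for basal and neuroendocrine epithelium (7.47 to 7.59) and 6.33 for thymocytes (6.72 to 6.96). Single mice also stood apart in the study-named genes (BALB/c control female 2, 6.72 against 5.84 to 6.11), basal and neuroendocrine epithelium (C3H/HeARC arsenic female 3, 7.06 against 7.35 to 7.47) and thymocytes (C57BL/6 control female 3, 7.38 against 6.71 to 6.82). The same held for inflammatory cytokines (BALB/c arsenic female 1, 6.57 against 6.83 to 6.98), cell cycle (C57BL/6 arsenic male 2, 6.42 against 7.46 to 7.99) and the glucocorticoid response (BALB/c control female 1, 10.25 against 9.09 to 9.50). It held too for erythroid genes (BALB/c control male 1, 7.99 against 7.83 to 7.89), muscle (C57BL/6 control female 1, 5.66 against 6.22 to 6.29) and adipose (C57BL/6 control male 3, 7.55 against 6.44 to 6.52). The arsenic effect differed between C57BL/6 and BALB/c by 0.884 in secretory and mucus, 2.44 in the study-named genes and 0.712 in the glucocorticoid response (adjusted p = 0.0344, 0.0155 and 0.048 with an estimated correlation, and 0 lists by fry). Without the 6 study-named genes the secretory and mucus difference was 0.334 (adjusted p = 0.194 with an estimated correlation). With 1 mouse left out these calls ended in 11, 1 and 23 of 34 cases, with adjusted p values up to 0.124, 0.0665 and 0.183. Without BALB/c control female 1 the glucocorticoid difference was 0.527 (adjusted p = 0.11).

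Other splits of the same mice were counted with the real split included. For lists past the preset test chance was not excluded: 94 of 100 splits gave as many in BALB/c (3, highest other 16), 15 in C3H/HeARC (15, highest other 20), 24 in C57BL/6 (13, highest other 19) and 63 for the mean of the strains (9, highest other 18). With 0 genes past the threshold by limma (unadjusted p under 0.05 in 548, 936, 676, 818, 646, 1302 and 345), all 100 splits give as many by construction, so these counts decide nothing on chance. The highest other counts were 82 in BALB/c, 1 in C3H/HeARC, 21 in C57BL/6, 4 for the mean, 9 for the strain difference, 2 for the sex difference and 0 for control sexes. The 10 splits of a single sex are too few for a share under 0.05, with 0 genes in each real split and 6, 0, 1 and 1 as highest others in BALB/c females, BALB/c males, C3H/HeARC females and C3H/HeARC males. Between control strains the real count was rarely reached, with 2 of 100 splits as large for BALB/c and C57BL/6 (1113, highest other 1688). It was 1 of 100 each for C3H/HeARC and C57BL/6 (1177, highest other 229) and for BALB/c and C3H/HeARC (914, highest other 376). In these last 2 comparisons the 1 is the real split, which argues against chance for their counts. The split with 1688 genes set 4 BALB/c controls against the 4 C57BL/6 controls together with BALB/c control female 3 and control male 3, so it largely follows the strains, with 2 mice moved, and points to a structure of the samples. The count of 1113 therefore does not isolate strain.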

How the results depend on the processing

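The settings without the 5 mice whose sex genes oppose their label, without C3H/HeARC control male 1, by permutation of list means, of the secretory and mucus list without study-named genes, and of the estimated correlation with 1 mouse left out were chosen only after the result was seen. Quantile normalization called 1 gene in C3H/HeARC and array weights 5, against 0. Within single sexes, every probe set gave 1 gene, all rows named or not 1 and array weights 25. Control strains gave 2488, 2207 and 2395 genes with array weights and 363, 753 and 452 without the 5 mice (BALB/c and C57BL/6, C3H/HeARC and C57BL/6, BALB/c and C3H/HeARC), and control sexes 6 without them. The 3 lists of BALB/c became 6 without the 5 mice, 12 with array weights, 6 with genes above the median level and 7 with samples of the strain only. With an estimated correlation 0 lists passed in BALB/c, C3H/HeARC and the mean and 2 in C57BL/6, and with fry 0, 0, 0 and 1. Leaving out 1 mouse gave 0 to 7 genes in C57BL/6, 0 to 3 in the mean, 0 to 6 for the strain difference, 0 to 1 for the sex difference, 0 to 17 in single sexes, 430 to 1333, 663 to 1265 and 594 to 1048 between control strains, and 3 to 8 lists in BALB/c and 8 to 16 in C57BL/6. The adipose list of C3H/HeARC was -0.024 with array weights, and -0.379 to -0.029 with 1 mouse left out, and muscle -0.862 to -0.012, both nearest 0 without control male 1. The cell cycle list of C57BL/6 was 0.049 with the same replicate numbers, and -0.265 to 0.031 with 1 mouse left out, positive without arsenic male 2. With the replicate number as a block, the arsenic comparisons stayed at 0 genes by limma, control strains gave 1073, 1079 and 892, and lists 9, 3, 15 and 10 in the mean, BALB/c, C3H/HeARC and C57BL/6. In C57BL/6 the block ended the calls of cell cycle (adjusted p = 0.0879), immediate early genes (0.0671) and lung development regulators (0.107). Arsenic and control mice of the same strain, sex and replicate number were compared by their deviations from the group means. These correlated over 0.1 in 6 of 16 pairs (-0.409 to 0.412). Groups held 2 or 3 mice and no expected spread was computed, so pairing of arsenic with control mice stays open. For females and males of the same strain, exposure and replicate number, no correlation was computed pair by pair. As a random effect over such mice, the replicate number gave a correlation of 0.0912, so a link between them stays open. Over single mice left out, 1283 list results kept direction and side of the threshold, 74 lost the call and in 3 the direction of the list test turned, with the mean itself changing sign for cell cycle alone. Most of these calls are within 1 strain, where leaving out a mouse of another strain cannot change the mean. The number of kept results therefore overstates how stable the calls are. With an estimated correlation, the secretory and mucus list of C57BL/6 lost the call without 3 mice (up to 0.116) and the study-named genes without 0 (0.0226 at most). Without the study-named genes, the secretory and mucus list of C57BL/6 was 0.269 (adjusted p = 0.238 with an estimated correlation). The random effect and robust variance were not run for lists, and the setting on a linear scale did not apply. Except where fewer mice or genes show it, the cause was not tested. Signal near the floor of 4 limits changes in 206 genes.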

Other observations

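The tests of lists between control strains were chosen only after the genes below were seen. Between control mice, 5, 12 and 16 of 31 lists passed with the preset correlation (BALB/c and C57BL/6, C3H/HeARC and C57BL/6, BALB/c and C3H/HeARC), and 0 with an estimated correlation. The values below are therefore read as single genes, and whether a cell type shifted stays undecided. Of all genes, 5.58%, 5.9% and 4.58% passed in these comparisons, and a sequence variant under a probe can lower a signal without a change in expression.

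Of 17 measured neutrophil genes, 10 gave a higher and 1 a lower signal in C3H/HeARC than in C57BL/6 controls, with a list mean of 0.97 (adjusted p = 0.113 with an estimated correlation). Among them were Ly6g, a neutrophil surface protein, at 2.41 (SE 0.28), Retnlg at 2.19 (SE 0.21) and the calcium-binding S100a8 at 1.75 (SE 0.28), and Lcn2 at -0.50 (SE 0.15). In BALB/c 7 of 17 were higher than in C57BL/6, such as S100a8 at 1.37 (SE 0.28) and S100a9 at 1.45 (SE 0.26), with a list mean of 0.66 (adjusted p = 0.778 with an estimated correlation). Of 23 endothelial genes, 7 gave a higher signal in BALB/c than in C57BL/6 controls, such as the vascular growth factor receptors Kdr at 0.69 (SE 0.12) and Flt1 at 0.56 (SE 0.12), with a list mean of 0.31 (adjusted p = 0.778 with an estimated correlation).

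The 2 most similar arrays were BALB/c control female 3 and control male 3. Similarity was measured by the scaled median absolute deviation of the log2 difference between 2 arrays, over genes of higher mean signal. It was 0.135 for this pair, against a median of 0.262 within groups and 0.318 between strains. Control male 3 is one of the mice whose sex genes oppose the label. The other such BALB/c mouse, control male 1, was among the 5 closest pairs too, with control female 2 at 0.162. The other 3 of these pairs were C57BL/6 control female 1 with control male 1 (0.157), BALB/c arsenic male 3 with control male 2 (0.158) and BALB/c arsenic male 2 with control female 2 (0.164). The pairs at 0.135 and 0.157 each share strain, exposure and replicate number, and the others of the 5 do not. Whether mice that share a replicate number are independent was not tested. C3H/HeARC control male 1 had the smallest array weight, 0.277, where the largest was 4.59.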
